A study of Rattus norvegicus with 57 samples.

How the data were processed

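The authors measured RNA from rat liver, prepared with RNeasy columns and labelled with the GeneChip 3' IVT Express kit, on Rat Genome 230 2.0 arrays, per the labels. The deposited values are MAS5 signals in a unit the authors call intensity, with no version of MAS5 given. They are on a linear scale, and a trimmed mean of 99.992 on each array (2% left out at each end) shows that every array was scaled to the same level. The table holds 31099 probe sets on 57 arrays without missing values, and 57 of the probe sets are controls. Raw scans were not reprocessed. Between arrays of the same group the median correlation of log2 signals was 0.974 and the lowest 0.961, against a median of 0.963 over all pairs, and the first 2 principal components held 33.2% and 7.39% of the variance.

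Of the probe sets, 20832 had 1 gene symbol in the array's annotation, 436 had several and 9831 had none. Of those with 1 symbol, 20764 matched by Entrez ID to the RefSeq gene table of assembly GRCr8, which was used for names and chromosomes. Signals were log2 transformed without an offset. A probe set was kept when it lay above the median of all values (17.09) in at least 4 arrays, which left 18677 and, among those with 1 symbol, 14341. For the 2759 genes with more than 1 such probe set, the probe set of the highest mean stood for the gene, giving 10725 genes. The others were left out except in the alternative that tests all probe sets.

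Tests used limma 3.58.1 in R 4.3.3, with means for the 12 groups of dose and day fitted to all arrays (lmFit), eBayes with a trend of the variance on the mean signal, and two-sided moderated tests. Each dose was compared with the control of the same day and with the other dose, and interactions compared the effect of a dose between days. P values were adjusted by Benjamini-Hochberg over the genes of a comparison and called under 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 28 lists of at least 5 measured genes, of 31 that were set from general knowledge of liver biology. In the main text the fold with an offset is the ratio after adding 3.31, the 20th percentile of all values, to each signal. Array measures were compared by exact permutation. Arrays were taken as independent, 1 animal each, since animals were housed singly per the labels. Permutation tests were run in R, and figures used matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

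Some lists share genes with other lists. The number of measured genes also held by another list was 2 (oxidative stress), 10 (cytochrome P450), 2 (bile acid), 1 (fatty acid oxidation), 7 (urea cycle and amino acid), 1 (plasma protein), 1 (acute phase), 1 (transcription factor), 5 (pericentral), 9 (periportal), 7 (male-biased), 2 (female-biased), 2 (biliary), 1 (macrophage), 1 (neutrophil), 1 (endothelial) and 1 (mast cell), and 0 for the rest.

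The comparisons, tests, lists, alternatives and the rule for naming genes were set before the data were examined. For each dose against control the rule names the 6 largest rises and 6 largest falls among called genes in which every treated array lay beyond every control array, without symbols that are only a number. For each list it adds up to 3 called members in the direction of the list's median and up to 2 against it. A gene so named may be given values in other comparisons. Between doses and in interactions it takes the 4 largest rises and 4 largest falls among called genes. The text takes genes in the order of the rule and does not name every gene it allows: to save length, their number was reduced to 233 results after the values were seen, and 1 gene was exchanged to keep the order. Alternatives were quantile normalization, arrays shifted to a common median, no filter, a stricter filter (mean above the 60th percentile), the offset, the mean of a gene's probe sets, all probe sets, no variance trend, array weights, only the groups compared, and each array left out in turn. For lists they were an estimated correlation and fry, which tests whether a list's genes move on balance one way. The actin 3'/5' ratio as a covariate, and leaving out the 2 day 24 arrays of the highest ratio (control replicate 4 and 30 mg/kg replicate 4), were chosen after seeing the data.

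The steps were tested on simulated data of 10725 genes with 50 changed at each fold of 1.5, 2, 3 and 4. For 80 mg/kg on day 4, 78%, 94%, 100% and 84% of them were called at these folds, with 9 unchanged genes. For 80 mg/kg on day 15 the shares were 96%, 96%, 100% and 98%, with 5. For 30 mg/kg they were 94%, 98%, 100% and 94% on day 15, with 14. On day 24 they were 90%, 100%, 96% and 80%, with 9. For the day 24 interaction at 80 mg/kg they were 72%, 84%, 92% and 66%, with 16. For 80 mg/kg on day 15, camera called the oxidative stress list at a shift of 0.5 log2 and not of 0, with 0 other lists at either. False list calls in correlated genes were not tested.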

Results

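Gene expression was measured in the livers of 57 male Han Wistar rats with Affymetrix Rat Genome 230 2.0 arrays, 1 array per animal. Methapyrilene, an antihistamine known to be toxic to rat liver, was given daily by gavage at 30 or 80 mg/kg, and control rats received the vehicle. Animals were sacrificed on day 4, 8 or 15, or on day 24 after 14 days of dosing and 10 days of recovery. Each of the 12 groups had 5 arrays, except control on day 24, 30 mg/kg on day 24 and 80 mg/kg on day 4, which had 4. The number of arrays limits the precision of each value. Each dose was compared with the control of the same day to ask which liver genes respond, the doses with each other to ask how the response grows, and day 24 with day 15 to ask how far it recedes after dosing. Over 10725 genes tested in each comparison, changes are given as log2 fold change ± standard error with limma's Benjamini-Hochberg adjusted p, and a gene passed under 0.05. Counts for gene lists are out of the genes measured, and limma's camera test is given with its adjusted p over 28 lists and with an estimated adjusted p, from a correlation between genes estimated for the list.

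More genes changed at the higher dose, where their number rose with days of dosing and was smaller after recovery. At 80 mg/kg, 2952 genes passed, 1966 up and 986 down on day 4. On day 8, 5446 genes passed, 3664 up and 1782 down. By day 15, 6354 genes passed, 4160 up and 2194 down, and after recovery 1097 genes passed, 767 up and 330 down. At 30 mg/kg, 84, 25, 493 and 10 genes passed on days 4, 8, 15 and 24. The split into rises and falls at 80 mg/kg depended on the scaling of the arrays. On the deposited scale the median change of all genes was 0.15 on day 8, 0.16 on day 15 and 0.04 on day 24. With every array shifted to a common median it was -0.07, 0.03 and -0.21, and on day 4 it moved from 0.08 to -0.05. With quantile normalization the median was 0.03 on day 8 and 0.04 on day 15. The calls at a common median were 943 up and 1596 down on day 4, 1772 up and 2996 down on day 8, 3099 up and 2790 down on day 15 and 267 up and 3359 down on day 24. With quantile normalization they were 2706 up and 2176 down on day 8, 3321 up and 2676 down on day 15 and 461 up and 311 down on day 24. At 30 mg/kg the split moved in the small counts of day 8, to 9 up and 5 down at a common median, and of day 24, to 6 up and 12 down with quantile normalization.

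**Figure D1:**
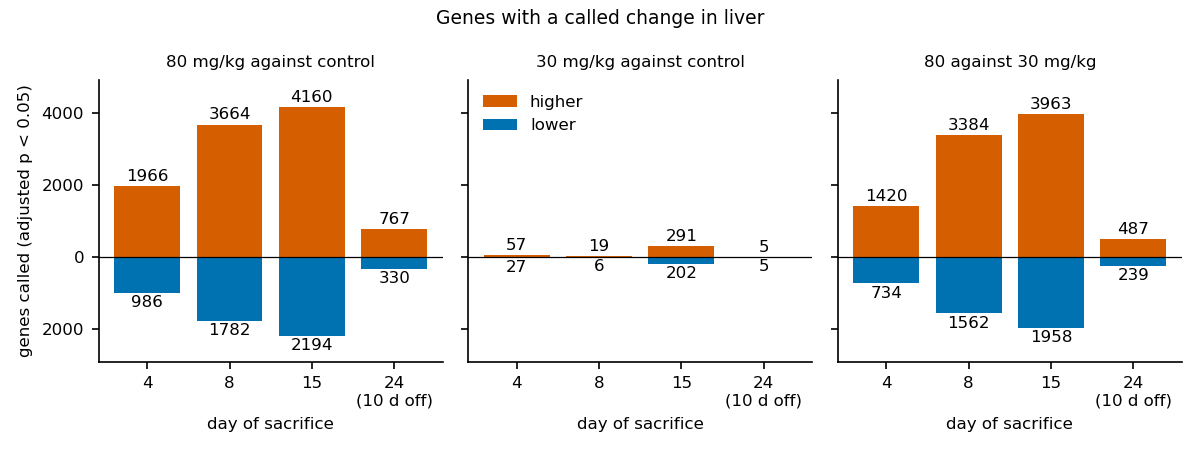
Number of genes with a called change (limma adjusted p under 0.05, vertical axis) by day of sacrifice, for each dose against control and for 80 against 30 mg/kg, on the deposited scale; bars above 0 count higher genes and bars below 0 count lower genes. At 80 mg/kg the bars reach 4160 higher and 2194 lower genes on day 15, and 767 and 330 on day 24; at a common median the day 24 split turns to 267 up and 3359 down.

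After 4 days at 80 mg/kg, camera called up 4 lists, of oxidative stress, p53 target, cell cycle and biliary genes, and called down 7 (4 arrays against 5). With an estimated correlation only the first 2 passed. The largest rise was in Acot1, an acyl-CoA thioesterase, at 5.56 ± 1.07, adjusted p = 7.63e-05. Its control signal of 1.25 is near the floor, and with an offset the change was 12.7-fold. Gstm3, a glutathione transferase, rose by 3.95 ± 0.73, adjusted p = 4.24e-05, and Akr1b7, an aldehyde reductase, by 3.89 ± 1.07, adjusted p = 0.00455. The largest falls were in Dab1, an adaptor of reelin signalling (-3.26 ± 0.44, adjusted p = 1.82e-07), Stac3, a muscle adaptor (-2.89 ± 0.43, adjusted p = 1.26e-06), and Hes5, a Notch target (-2.22 ± 0.71, adjusted p = 0.0151).

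Under stress, 14 of 26 oxidative stress genes driven by Nrf2 rose (16 adjusted over the list alone, camera adjusted p = 1.47e-07, estimated adjusted p = 0.0321). They included the transporter Abcc3 (3.42 ± 0.41) and Gsta3 (3.04 ± 0.30). In turn, 10 of 16 p53 target genes rose (10 adjusted over the list alone, camera adjusted p = 0.00179, estimated adjusted p = 0.0321). They were led by the growth arrest gene Gadd45a (2.12 ± 0.39), Ddit4l (1.53 ± 0.40) and the death receptor Fas (1.10 ± 0.18). The ER stress and ATF4 list split, as 8 of 29 genes rose and 6 fell (8 and 7 adjusted over the list alone, camera adjusted p = 0.76), with median 0.12, mean 0.52, test down. The ATF4 targets Trib3, a pseudokinase (3.56 ± 0.36), Fgf21, a hormone (3.12 ± 0.38), and Phgdh, of serine synthesis (2.89 ± 0.75), rose, and Sel1l (-0.67 ± 0.096) and Herpud1 (-0.61 ± 0.23), of ER-associated degradation, fell. For division, 37 of 40 cell cycle genes rose (40 adjusted over the list alone, camera adjusted p = 1.67e-15, estimated adjusted p = 0.301). They included cyclin Ccna2 (3.07 ± 0.53), Cdkn3 (2.84 ± 0.65) and the spindle kinase Ttk (2.57 ± 0.99). Among cell markers, 10 of 20 biliary and progenitor genes rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.0398, estimated adjusted p = 0.417). They included the tight junction genes Cldn7 (2.45 ± 0.75) and Cldn4 (2.16 ± 0.67) and Ggt1 (1.67 ± 0.30). The macrophage list did not pass by camera. Here 3 of 24 genes rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.642), with the attractant Ccl2 (2.98 ± 0.57) and Gpnmb (1.06 ± 0.27) up and Cd14 (-0.56 ± 0.14) down.

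By limma, 9 of 16 male-biased genes fell (9 adjusted over the list alone, camera adjusted p = 2.54e-05, estimated adjusted p = 0.317). Among them were the peroxisomal oxidase Hao2 (-1.63 ± 0.27), Ust5r (-1.05 ± 0.25) and the urinary protein Mup5 (-0.88 ± 0.25). Next, 1 of 33 urea cycle and amino acid genes rose and 13 fell (1 and 15 adjusted over the list alone, camera adjusted p = 4.38e-05, estimated adjusted p = 0.455). They included serine dehydratase Sds (-2.18 ± 0.55) and the transaminase Gpt2 (-1.02 ± 0.24), with argininosuccinate lyase Asl up (0.62 ± 0.13). Also, 1 of 19 fatty acid synthesis genes rose and 9 fell (2 and 10 adjusted over the list alone, camera adjusted p = 7.73e-04, estimated adjusted p = 0.381). They included pyruvate kinase Pklr (-1.48 ± 0.24) and the desaturase Scd (-1.45 ± 0.42). Then 8 of 28 plasma protein genes fell (9 adjusted over the list alone, camera adjusted p = 0.00318, estimated adjusted p = 0.728). They included Apoa4 (-2.04 ± 0.25) and coagulation factor F10 (-0.49 ± 0.081). That list's median of 0.02 has another sign than its mean of -0.13 and its downward test, and turned to -0.01 with quantile normalization and -0.11 at a common median. Camera also called down bile acid, pericentral and xenobiotic cytochrome P450 genes, with 3, 2 and 2 rising and 7, 7 and 6 falling of 23, 17 and 24 (3, 2 and 2 up and 8, 8 and 6 down adjusted over the list alone). Their camera adjusted p = 0.00643, 0.00558 and 0.0127, and estimated adjusted p = 0.417, 0.301 and 0.728. All 4 treated arrays lay on the stated side of the control mean for each gene named, and beyond every control array except for Herpud1 (0 of 4) and Mup5 (3 of 4). Leave-one-out fits ended the calls of Hes5 and Scd (without 80 mg/kg replicate 5, adjusted p = 0.0587 and 0.0618), Cldn7 (without control replicate 1, adjusted p = 0.0536) and Cldn4 (without control replicate 3 or 80 mg/kg replicate 5, adjusted p = 0.0535 and 0.0726). Of 9 such fits each, calls also ended for Herpud1 in 6 (adjusted p up to 0.126) and Ttk in 7 (adjusted p up to 0.14). In other settings, another scaling and an actin alternative ended the calls of Herpud1 and Ttk, another filter, offset, probe set or variance choice those of Ttk and Gpt2, a fit of only the groups compared those of Herpud1, and a replicate block those of Ttk.

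By day 8 at 80 mg/kg camera called up 4 lists, of oxidative stress, p53 target, cell cycle and macrophage genes, and called down 14 (5 arrays against 5). Of these 18 calls 0 held with an estimated correlation (smallest estimated adjusted p = 0.0651), while fry called 20. Acot1 rose by 7.88 ± 1.01, adjusted p = 6.12e-09, Phgdh by 5.72 ± 0.71, adjusted p = 2.82e-09 and Gucy2c, a guanylate cyclase receptor, by 5.28 ± 0.73, adjusted p = 3.82e-08. Their control signals of 1.16, 5.01 and 1.58 are near the floor, and with an offset the changes were 51.6-fold, 26.5-fold and 11.5-fold. Stac3 fell furthest (-5.98 ± 0.41, adjusted p = 2.41e-16), from a control signal of 2374 to 37.6, followed by the oxidase Nox4 (-3.89 ± 0.45) and the methyltransferase Inmt (-3.80 ± 0.47). In the stress lists, 15 of 26 oxidative stress genes rose (15 adjusted over the list alone, camera adjusted p = 1.26e-05, estimated adjusted p = 0.07). They included Abcc3 (4.86 ± 0.39), Gsta3 (4.43 ± 0.28) and Gstm3 (4.30 ± 0.69). In turn, 10 of 16 p53 targets rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 0.00725, estimated adjusted p = 0.07). They included Ddit4l (2.29 ± 0.38), Gadd45a (2.11 ± 0.37) and the cell cycle inhibitor Cdkn1a (1.66 ± 0.21). The ER stress and ATF4 list split again, as 12 of 29 genes rose and 9 fell (12 and 9 adjusted over the list alone, camera adjusted p = 0.653), with median -0.06, mean 0.75, test down. Trib3 (4.36 ± 0.34) and Phgdh rose and the ER folding and degradation genes Sdf2l1 (-1.08 ± 0.13), Sel1l (-0.87 ± 0.09) and Pdia4 (-0.86 ± 0.091) fell. In division, 39 of 40 cell cycle genes rose (40 adjusted over the list alone, camera adjusted p = 2.37e-09, estimated adjusted p = 0.25). They included Ttk (3.48 ± 0.93) and Ccna2 (3.40 ± 0.50). In immune cells, 19 of 24 macrophage markers rose and 1 fell (19 and 1 adjusted over the list alone, camera adjusted p = 3e-04, estimated adjusted p = 0.309). Gpnmb (2.36 ± 0.25), galectin Lgals3 (1.56 ± 0.20) and Ccl2 (1.51 ± 0.54) rose and Cd14 fell (-0.73 ± 0.13).

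Of the sex-biased genes, 15 of 16 male-biased genes fell (15 adjusted over the list alone, camera adjusted p = 8.91e-12, estimated adjusted p = 0.0651). They included Hao2 (-3.06 ± 0.26), Ust5r (-2.66 ± 0.24) and the urinary carrier Obp3 (-1.98 ± 0.34). In turn, 3 of 10 female-biased genes rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.874), with median -0.07, mean 0.55, test down. Cyp2c12 rose (4.05 ± 0.51, adjusted p = 4.98e-09) and Cyp2c11 fell (-1.58 ± 0.22, adjusted p = 3.75e-08). For bile acids, 3 of 23 genes rose and 14 fell (3 and 16 adjusted over the list alone, camera adjusted p = 5.73e-06, estimated adjusted p = 0.0813). The uptake carrier Slc10a1 fell (-1.32 ± 0.16) and the exporters Abcc4 (1.94 ± 0.20) and Abcc2 (0.91 ± 0.11) rose. In fat use, 6 of 26 fatty acid oxidation genes rose and 11 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.00422, estimated adjusted p = 0.346). Their median of -0.19 (-0.0024 with quantile normalization, -0.41 at a common median) and downward test have another sign than their mean of 0.28, with Hadh down (-0.98 ± 0.082) and the thioesterases Acot1 and Acot2 (2.48 ± 0.21) up. Next, 1 of 33 urea cycle and amino acid genes rose and 28 fell (1 and 28 adjusted over the list alone, camera adjusted p = 3.29e-13, estimated adjusted p = 0.0813). They included Sds (-3.35 ± 0.51) and histidase Hal (-1.93 ± 0.23), with Asl up (0.86 ± 0.12). Then 25 of 28 plasma protein genes fell (25 adjusted over the list alone, camera adjusted p = 9.8e-15, estimated adjusted p = 0.119). They included Apoa4 (-2.75 ± 0.24) and F10 (-0.96 ± 0.077). In turn, 2 of 24 acute phase genes rose and 16 fell (4 and 16 adjusted over the list alone, camera adjusted p = 4.05e-05, estimated adjusted p = 0.205), with A2m down (-2.62 ± 0.38) and lipocalin Lcn2 up (1.41 ± 0.25). Camera also called down xenobiotic cytochrome P450, fatty acid synthesis and mitochondrial genes, with 2, 1 and 3 rising and 19, 11 and 19 falling of 24, 19 and 30 (2, 1 and 4 up and 19, 11 and 22 down adjusted over the list alone). Camera gave adjusted p = 1.48e-09, 1.04e-05 and 2.27e-05, and estimated adjusted p = 0.0813, 0.119 and 0.254. With quantile normalization the mitochondrial median of -0.20 turned to 0.01, and the plasma protein and acute phase medians of -0.54 and -0.44 shrank to -0.14 and -0.07. At a common median the 3 were -0.42, -0.76 and -0.66. On day 8, all 5 treated arrays lay on the stated side of the control mean for each gene named, and beyond every control array except for Ttk (4 of 5) and Cd14 (4 of 5). Leave-one-out fits ended the call of Ccl2 (without control replicate 4, adjusted p = 0.0803).

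On day 15 at 80 mg/kg changes were the most numerous of any comparison with control (5 arrays against 5). Acot1 rose by 10.99 ± 1.01, adjusted p = 1.85e-13, Phgdh by 6.48 ± 0.71, adjusted p = 3.61e-11 and Gucy2c by 6.32 ± 0.73, adjusted p = 1.66e-10. Control signals were again near the floor (0.913, 5.08 and 1.62), and with an offset the changes were 375-fold, 51.9-fold and 25.7-fold. Stac3 (-7.20 ± 0.41, adjusted p = 2.57e-20), Sds (-4.64 ± 0.51, adjusted p = 5.04e-11) and Mmd2, a membrane protein (-4.35 ± 0.49, adjusted p = 1.02e-10), fell furthest. Of the stress lists, 16 of 26 oxidative stress genes rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 0.00211, estimated adjusted p = 0.164). They included Gstm3 (4.91 ± 0.69), Akr1b8 (4.33 ± 0.33) and the glutathione peroxidase Gpx2 (4.25 ± 0.80). In turn, 12 of 16 p53 targets rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.00893, estimated adjusted p = 0.104). They included Gadd45a (2.50 ± 0.37), Ddit4l (2.43 ± 0.38) and Tp53inp1 (1.998 ± 0.31). In the ER stress and ATF4 list 13 of 29 genes rose and 12 fell (13 and 12 adjusted over the list alone, camera adjusted p = 0.481), with median -0.10, mean 1.01, test down. Trib3 (4.89 ± 0.34) and Phgdh rose, and Sdf2l1 (-1.66 ± 0.13), Hyou1 (-1.26 ± 0.20) and Sel1l (-1.26 ± 0.09) fell. In division, 37 of 40 cell cycle genes rose (37 adjusted over the list alone, camera adjusted p = 2.65e-04, estimated adjusted p = 0.496). They included Ttk (3.60 ± 0.93) and the mitotic kinase Pbk (2.98 ± 0.50). Of cell markers, 14 of 20 biliary and progenitor genes rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 0.0145, estimated adjusted p = 0.198). Cldn7 (3.29 ± 0.70), Ggt1 (2.80 ± 0.28) and Cd24 (2.71 ± 0.24) rose and the liver factor Onecut2 fell (-1.06 ± 0.12). The macrophage list did not pass, although 15 of 24 genes rose and 1 fell (15 and 1 adjusted over the list alone, camera adjusted p = 0.115). They included Gpnmb (2.82 ± 0.25) and Ccl2 (1.60 ± 0.54).

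Of sex-biased genes, 15 of 16 male-biased genes fell (15 adjusted over the list alone, camera adjusted p = 1.34e-10, estimated adjusted p = 0.1). They included Hao2 (-3.33 ± 0.26) and Obp3 (-3.33 ± 0.34), while Cyp2c12 rose (3.76 ± 0.51). In xenobiotic metabolism, 2 of 24 cytochrome P450 genes rose and 19 fell (2 and 19 adjusted over the list alone, camera adjusted p = 5.46e-09, estimated adjusted p = 0.153). Cyp2c11 (-2.10 ± 0.22) and Cyp2c7 (-2.04 ± 0.32) fell and Cyp1a1 rose (3.46 ± 0.83). For bile acids, 3 of 23 genes rose and 16 fell (3 and 16 adjusted over the list alone, camera adjusted p = 1.82e-06, estimated adjusted p = 0.104). The uptake carriers Slc10a1 (-1.99 ± 0.16) and Slco1a4 (-1.78 ± 0.18) fell and the exporters Abcc4 (2.88 ± 0.20) and Abcc2 (1.16 ± 0.11) rose. In fat synthesis, 1 of 19 genes rose and 13 fell (1 and 13 adjusted over the list alone, camera adjusted p = 8.52e-06, estimated adjusted p = 0.153). They included Scd (-2.90 ± 0.40), Pklr (-2.58 ± 0.23) and Thrsp (-2.43 ± 0.29). The oxidation list did not pass (10 of 26 genes rose and 11 fell, 10 and 11 adjusted over the list alone, camera adjusted p = 0.261, median 0.22, mean 0.60, test down), with Acot2 (3.38 ± 0.21) and Hadhb (1.09 ± 0.088) up and Hadh (-1.25 ± 0.082) and the carrier Fabp1 (-0.95 ± 0.11) down. Next, 2 of 33 urea cycle and amino acid genes rose and 29 fell (2 and 29 adjusted over the list alone, camera adjusted p = 4.53e-11, estimated adjusted p = 0.153). Hal fell (-2.68 ± 0.23) and Asl (1.25 ± 0.12) and tyrosine aminotransferase Tat (1.09 ± 0.21) rose. Then 1 of 28 plasma protein genes rose and 25 fell (1 and 25 adjusted over the list alone, camera adjusted p = 2.31e-13, estimated adjusted p = 0.164). Apoa4 (-2.19 ± 0.24) and complement C9 (-1.64 ± 0.13) fell and Igfbp1 rose (1.39 ± 0.35). In the acute phase, 2 of 24 genes rose and 16 fell (2 and 16 adjusted over the list alone, camera adjusted p = 8.78e-06, estimated adjusted p = 0.164). Il1rn (-2.92 ± 0.66), A2m (-2.87 ± 0.38) and Serpina3n (-2.05 ± 0.17) fell, and metallothionein Mt2A (2.52 ± 0.44) and Lcn2 (1.58 ± 0.25) rose. Of blood markers, 4 of 6 red blood cell genes fell (4 adjusted over the list alone, camera adjusted p = 0.0266, estimated adjusted p = 0.414). They included Slc4a1 (-1.32 ± 0.30) and Hba-a3 (-1.23 ± 0.25).

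Camera also called down periportal, pericentral, liver transcription factor and cholesterol synthesis genes, with 2 each rising and 14, 7, 11 and 8 falling of 20, 17, 19 and 19 (2 each up and 14, 7, 11 and 8 down adjusted over the list alone). By camera, adjusted p = 8.78e-06, 0.0106, 0.0017 and 0.0106, and estimated adjusted p = 0.164, 0.164, 0.1 and 0.482. Of the 28 lists, 16 passed. In 4 further lists without a call, median, mean and test differed in sign. Here 3 of 10 female-biased genes rose and 5 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.195), with median -0.58, mean 0.05, test down. Next, 5 of 17 circadian clock genes rose and 7 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.235), with median -0.21, mean 0.01, test down. Then 9 of 29 stellate cell genes rose and 5 fell (8 and 4 adjusted over the list alone, camera adjusted p = 0.411), with median 0.04, mean 0.16, test down. Last, 1 of 5 muscle genes rose (1 adjusted over the list alone, camera adjusted p = 0.872), with median 0.11, mean 0.54, test down. Across day 15, all 5 treated arrays lay on the stated side of the control mean for each gene named, and beyond every control array except for Igfbp1 (4 of 5), Ccl2 (4 of 5) and Slc4a1 (4 of 5). Each call of a gene named here held in every leave-one-out fit and in every other setting that gave a value.

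**Figure D2:**
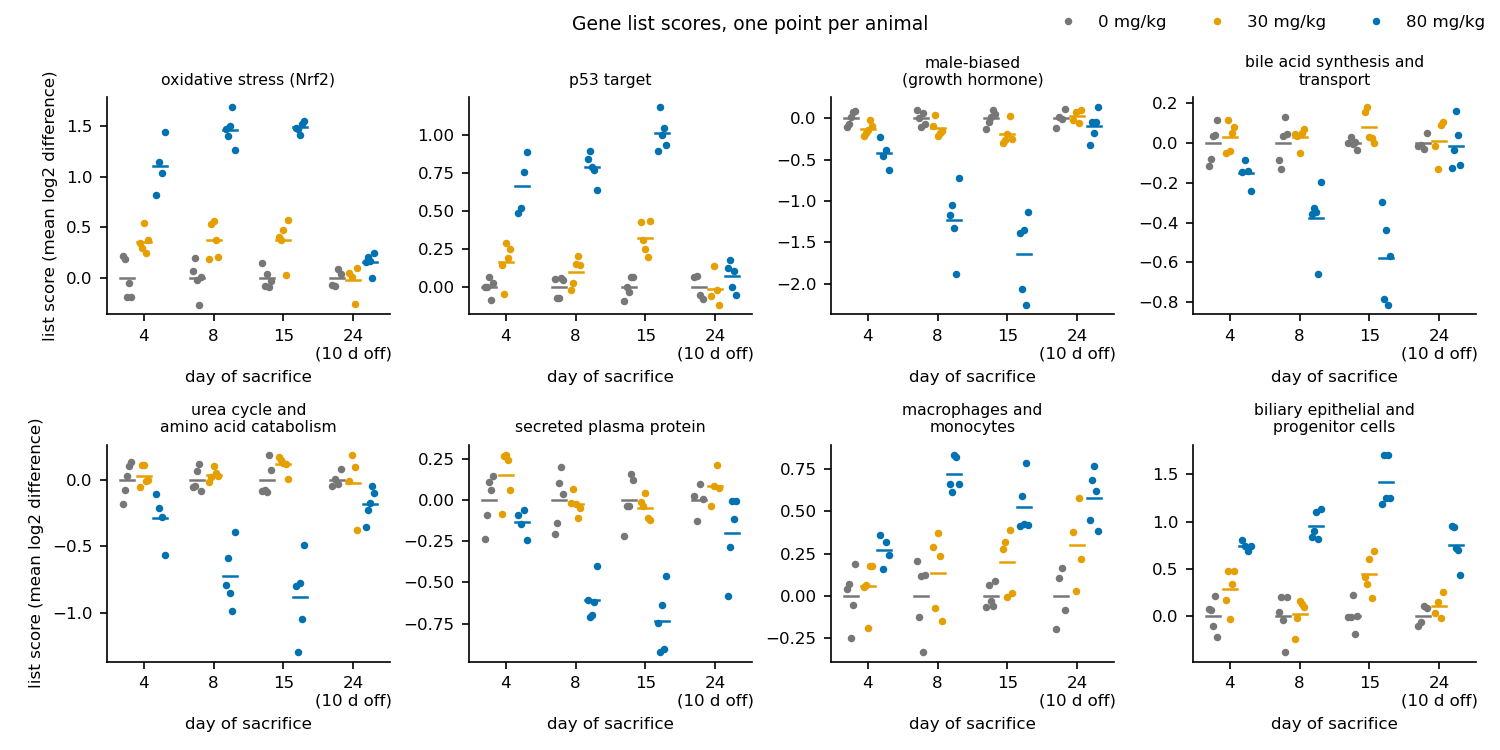
Scores of 8 gene lists per animal (vertical axis, mean over the list's genes of the log2 difference to the mean of the day's control arrays) by day of sacrifice and dose; points are animals and short lines are group means. At 80 mg/kg the male-biased list lies lowest on day 15 (mean log2 fold change -1.64), and the biliary and macrophage lists stay above control on day 24 (0.75 and 0.58).

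After 10 days without dosing from 80 mg/kg, camera called up markers of macrophages and of stellate, biliary, lymphoid and endothelial cells (5 arrays against 4). Of its 13 calls 0 passed with an estimated correlation (smallest estimated adjusted p = 0.0647), and fry called 7. The size of these 5 depended on the scaling: the list medians of 0.60, 0.48, 0.79, 0.69 and 0.37 became 0.35, 0.22, 0.54, 0.44 and 0.11 at a common median, as the 80 mg/kg arrays had the higher medians. With the 2 day 24 arrays of the highest actin 3'/5' ratio left out, 1 of them a control, 1063 genes passed, and with all arrays 1097. Leaving out those arrays was chosen after seeing the data. Phgdh was still raised (3.45 ± 0.75, adjusted p = 0.00233), with the hyaluronan synthase Has2 (2.34 ± 0.51, adjusted p = 0.00242) and the thyroxine carrier Serpina7 (2.27 ± 0.50, adjusted p = 0.00268). With an offset Phgdh changed 4.38-fold and Has2 2.75-fold. The keratin Krt14 also rose (2.25 ± 0.67), and the phosphatase Synj2 (-1.995 ± 0.56) and Elapor1 (-1.38 ± 0.28) fell. Among cell markers 17 of 24 macrophage genes rose (19 adjusted over the list alone, camera adjusted p = 1.76e-11, estimated adjusted p = 0.151). They included Gpnmb (0.97 ± 0.27), complement C1qb (0.83 ± 0.13) and Adgre1 (0.78 ± 0.18). For matrix, 14 of 29 stellate cell genes rose (16 adjusted over the list alone, camera adjusted p = 7.61e-07, estimated adjusted p = 0.247). They included decorin Dcn (1.18 ± 0.38), Mfap4 (1.01 ± 0.29) and collagen Col1a1 (0.96 ± 0.30). For ducts, 6 of 20 biliary and progenitor genes rose (13 adjusted over the list alone, camera adjusted p = 3.32e-06, estimated adjusted p = 0.0647). They included Prom1 (1.34 ± 0.27), Epcam (1.12 ± 0.24) and Cd24 (1.10 ± 0.26). For vessels, 7 of 20 endothelial genes rose (8 adjusted over the list alone, camera adjusted p = 3.19e-05, estimated adjusted p = 0.151). They included Ramp2 (0.71 ± 0.13), Mmrn2 (0.65 ± 0.17) and Pecam1 (0.59 ± 0.15). For lymphoid cells, 4 of 12 genes rose (7 adjusted over the list alone, camera adjusted p = 4.59e-04, estimated adjusted p = 0.151). They included Gzmk (0.83 ± 0.23) and Ccl5 (0.79 ± 0.23). Of the mast cell markers, too few for a list test, Mcpt1 (2.39 ± 0.73) and Cpa3 (1.23 ± 0.23) rose.

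Camera also called cell cycle genes (0 of 40 genes passed in limma, 12 at an unadjusted p under 0.05, 0 adjusted over the list alone, camera adjusted p = 0.00808, estimated adjusted p = 0.662) up on day 24. It called down mitochondrial, plasma protein, urea cycle and amino acid and periportal genes, with 2, 0, 1 and 2 falling of 30, 28, 33 and 20 (9, 0, 1 and 2 down adjusted over the list alone, 13, 9, 7 and 6 at an unadjusted p under 0.05). In camera, these had adjusted p = 9.29e-08, 4.33e-07, 3.19e-05 and 1.86e-04, and estimated adjusted p = 0.247, 0.433, 0.433 and 0.386. Further down were fatty acid synthesis, fatty acid oxidation and xenobiotic cytochrome P450 genes, with 1, 2 and 0 falling of 19, 26 and 24 (1, 3 and 0 down adjusted over the list alone, 6, 8 and 2 at an unadjusted p under 0.05). Their camera adjusted p = 0.00123, 0.00182 and 0.00227, and estimated adjusted p = 0.431, 0.433 and 0.494. With quantile normalization the medians of these 7 lists shrank, the plasma protein one from -0.19 to -0.02 and the cytochrome P450 one from -0.12 to -0.01, while at a common median these 2 were -0.44 and -0.37. On day 24, all 5 treated arrays lay on the stated side of the control mean for each gene named, and beyond every control array except for Col1a1 (1 of 5), Gpnmb (4 of 5), Mmrn2 (4 of 5), Gzmk (2 of 5), Ccl5 (4 of 5) and Mcpt1 (4 of 5). Single arrays moved the count of genes at 80 mg/kg, to 611 without control replicate 3, 693 without control replicate 5 and 683 without 80 mg/kg replicate 2. Leave-one-out fits ended the calls of Mfap4 (without control replicate 3 or control replicate 5, adjusted p = 0.0675 and 0.0676), Gpnmb and Pecam1 (without control replicate 5, adjusted p = 0.0841 and 0.0732), Mmrn2 (without control replicate 2, adjusted p = 0.0515), Gzmk (without control replicate 2 or control replicate 5, adjusted p = 0.0684 and 0.0933) and Ccl5 (without control replicate 2 or 80 mg/kg replicate 1, adjusted p = 0.0585 and 0.0947). Of 9 such fits each, calls also ended for Krt14 in 3 (adjusted p up to 0.117), Synj2 in 3 (adjusted p up to 0.0878), Dcn in 7 (adjusted p up to 0.0991), Col1a1 in 5 (adjusted p up to 0.156) and Mcpt1 in 5 (adjusted p up to 0.0954). In other settings, another scaling ended the calls of Dcn, Mfap4, Col1a1, Mmrn2, Gzmk, Mcpt1, Pecam1 and Ccl5, a fit of only the groups compared those of Synj2, Col1a1, Mmrn2, Gzmk and Mcpt1, a replicate block those of Synj2, and an actin alternative those of Dcn and Mcpt1.

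At 30 mg/kg fewer genes passed on days 4 and 8 than on day 15 (5 arrays against 5 on each day). On day 4 Gsta3 (1.82 ± 0.28, adjusted p = 0.000289) and the aldehyde dehydrogenase Aldh1a1 (1.45 ± 0.28, adjusted p = 0.00737) rose, with the aflatoxin reductase Akr7a3 (0.91 ± 0.20), the phosphatase Ptpn7 (1.66 ± 0.39) and the adaptor Ap1m2 (1.63 ± 0.35). Fgf21 (1.48 ± 0.36) and Fas (0.69 ± 0.17) rose as well, and the ephrin Efna5 (-0.90 ± 0.18) and Fam168a (-0.86 ± 0.21) fell. Camera called up oxidative stress genes (3 of 26 genes rose, 9 adjusted over the list alone, camera adjusted p = 9.96e-05, estimated adjusted p = 0.248) and mitochondrial genes (2 of 30 genes rose, 13 adjusted over the list alone, camera adjusted p = 4.72e-11, estimated adjusted p = 0.248). It also called up cell cycle, fatty acid oxidation, plasma protein and acute phase genes, with 0 each passing in limma of 40, 26, 28 and 24 (0, 1, 0 and 0 up adjusted over the list alone, 6, 5, 13 and 8 at an unadjusted p under 0.05). Camera gave adjusted p = 9.96e-05, 0.0077, 1.01e-04 and 0.0077, and estimated adjusted p = 0.748 each. The medians of the plasma protein and acute phase lists, 0.21 and 0.16, turned below 0 with quantile normalization. On day 4, all 5 treated arrays lay on the stated side of the control mean for each gene named, and beyond every control array except for Akr7a3 (4 of 5), Fas (4 of 5) and Fgf21 (4 of 5). The count of 84 genes became 19 without control replicate 2, 27 without control replicate 3, 43 without 30 mg/kg replicate 1, 23 without 30 mg/kg replicate 2, 51 without 30 mg/kg replicate 3, 48 without 30 mg/kg replicate 4 and 32 without 30 mg/kg replicate 5, and 2 with a fit of only the groups compared. The count of 6 lists became 10 without control replicate 4 and 13 without 30 mg/kg replicate 1. Single arrays left out ended the calls of Ap1m2 (without control replicate 4 or 30 mg/kg replicate 2, adjusted p = 0.0553 and 0.0721). Of 10 such fits each, calls also ended for Ptpn7 in 3 (adjusted p up to 0.13), Akr7a3 in 4 (adjusted p up to 0.0796), Fam168a in 6 (adjusted p up to 0.128), Fas in 8 (adjusted p up to 0.128) and Fgf21 in 6 (adjusted p up to 0.107). Otherwise, another scaling, another filter, offset, probe set or variance choice, a replicate block and an actin alternative ended the calls of Fas, and a fit of only the groups compared those of Ptpn7, Ap1m2, Aldh1a1, Akr7a3, Efna5, Fam168a, Fas and Fgf21.

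On day 8 at 30 mg/kg Akr1b7 rose most (5.93 ± 1, adjusted p = 0.000674), 26.2-fold with an offset, followed by Gsta3 (2.65 ± 0.28, adjusted p = 1.17e-08), Fgf21 (1.95 ± 0.36, adjusted p = 0.00255) and Aldh1a1 (1.86 ± 0.28, adjusted p = 0.000159). The sugar acid enzyme Cryl1 (1.25 ± 0.21) and Akr7a3 (1.22 ± 0.20) rose, and Ildr2, of lipid metabolism (-1.91 ± 0.39), and Nrbp2 (-0.80 ± 0.16) fell. Camera called up oxidative stress genes (3 of 26 genes rose, 7 adjusted over the list alone, camera adjusted p = 4.68e-05, estimated adjusted p = 0.268). Also up were female-biased, heat shock, cell cycle and macrophage genes, with 0 each passing in limma of 10, 15, 40 and 24 (2, 1, 1 and 0 up adjusted over the list alone, 4, 3, 2 and 4 at an unadjusted p under 0.05). By camera, adjusted p = 0.00656, 0.0182, 0.00102 and 0.0168, and estimated adjusted p = 0.333, 0.733, 0.939 and 0.939. It called down cholesterol synthesis, fatty acid synthesis and stellate cell genes, with 0 each passing in limma of 19, 19 and 29 (0, 2 and 1 down adjusted over the list alone, 5, 4 and 6 at an unadjusted p under 0.05). In camera, these had adjusted p = 8.39e-04, 0.0116 and 0.00102, and estimated adjusted p = 0.733 each. By selection all 5 treated arrays lay beyond all controls for each gene named. The count of 25 genes became 15 without control replicate 1, 43 without control replicate 3 and 12 without 30 mg/kg replicate 3, and the count of 8 lists 5 without 30 mg/kg replicate 4. Single arrays left out ended the call of Ildr2 (without 30 mg/kg replicate 2 or 30 mg/kg replicate 3, adjusted p = 0.0616 and 0.0691). Otherwise, a fit of only the groups compared ended the calls of Akr1b7 and Ildr2.

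Changes at 30 mg/kg were most numerous on day 15 (5 arrays against 5). Fgf21 (3.97 ± 0.36, adjusted p = 7.57e-11), Phgdh (3.92 ± 0.71, adjusted p = 0.000449) and the clock-linked deadenylase Noct (3.58 ± 0.64, adjusted p = 0.000386) rose, Phgdh by 9.06-fold with an offset. The control signal of Noct was lower on this day (51.9) than on days 4, 8 and 24 (188, 189 and 430), while at 30 mg/kg it was 620 and 277, 558 and 475. In the control arrays limma called 111 genes for the replicate number, 23 of them also at 30 mg/kg on day 15. Also up were Gem, a small GTPase (2.97 ± 0.54), and Ddit4, an mTOR inhibitor (2.86 ± 0.45), while Dab1 (-2.07 ± 0.42) and Nfe2 (-1.70 ± 0.43) fell. In the ER stress and ATF4 list 10 of 29 genes rose and 4 fell (11 and 9 adjusted over the list alone, camera adjusted p = 0.0312, estimated adjusted p = 0.738). Hyou1 (-0.66 ± 0.20) and Pdia4 (-0.46 ± 0.091) fell. Of the stress lists, 3 of 26 oxidative stress genes rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.0137, estimated adjusted p = 0.574), with Gsta3 (2.13 ± 0.28), Aldh1a1 (1.66 ± 0.28) and Akr7a3 (1.13 ± 0.20) up and Osgin1 (-1.14 ± 0.34) down. In turn, 3 of 16 p53 targets rose (4 adjusted over the list alone, camera adjusted p = 0.0264, estimated adjusted p = 0.387). They included Gadd45a (1.24 ± 0.37), Tp53inp1 (1.22 ± 0.31) and Cdkn1a (0.70 ± 0.21). In fat use, 4 of 26 fatty acid oxidation genes rose (5 adjusted over the list alone, camera adjusted p = 0.0126, estimated adjusted p = 0.738). They included Acot1 (3.27 ± 1.01, but 2.53-fold with an offset from a signal of 0.913 to 8.83, both near the floor), Acot2 (1.09 ± 0.21) and the coactivator Ppargc1a (0.98 ± 0.23). In the clock, 3 of 17 genes rose (4 adjusted over the list alone, camera adjusted p = 0.0312, estimated adjusted p = 0.387). They included Dbp (1.26 ± 0.31) and Nfil3 (0.76 ± 0.19). The amino acid enzymes Tat (1.24 ± 0.21) and Asl (0.61 ± 0.12) and the binding protein Igfbp1 (1.66 ± 0.35) rose.

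Camera further called up cell cycle, biliary, macrophage, mitochondrial and heat shock genes, with 1, 1, 0, 2 and 2 rising of 40, 20, 24, 30 and 15 (1, 4, 0, 2 and 4 up and 0, 1, 0, 0 and 0 down adjusted over the list alone, 18, 10, 4, 6 and 4 at an unadjusted p under 0.05). Their camera adjusted p = 1.43e-04, 0.0158, 0.0137, 0.0264 and 0.0312, and estimated adjusted p = 0.738, 0.557, 0.738, 0.738 and 0.738. It called down plasma protein and male-biased genes, with 1 and 0 rising and 2 and 0 falling of 28 and 16 (1 and 0 up and 2 and 3 down adjusted over the list alone, 7 and 4 at an unadjusted p under 0.05). Camera gave adjusted p = 0.031 and 0.0312, and estimated adjusted p = 0.871 and 0.738. At this dose, all 5 treated arrays lay on the stated side of the control mean for each gene named, and beyond every control array except for Akr7a3 (4 of 5), Gadd45a (4 of 5), Tp53inp1 (4 of 5), Cdkn1a (4 of 5), Hyou1 (4 of 5) and Acot1 (4 of 5). The count of 493 genes became 277 without 30 mg/kg replicate 1, 281 without 30 mg/kg replicate 2 and 280 without 30 mg/kg replicate 5, and the count of 12 lists 7 without 30 mg/kg replicate 5. Single arrays left out ended the calls of Nfe2 (without 30 mg/kg replicate 5, adjusted p = 0.0528) and Tp53inp1 (without control replicate 1 or 30 mg/kg replicate 1, adjusted p = 0.0531 and 0.0574). Of 10 such fits each, calls also ended for Osgin1 in 8 (adjusted p up to 0.111), Gadd45a in 8 (adjusted p up to 0.149), Cdkn1a in 8 (adjusted p up to 0.109), Hyou1 in 8 (adjusted p up to 0.111) and Acot1 in 6 (adjusted p up to 0.163). Otherwise, another scaling, another filter, offset, probe set or variance choice and an actin alternative ended the calls of Hyou1, Acot1, Gadd45a and Cdkn1a, a fit of only the groups compared those of Acot1, and a replicate block those of Cdkn1a, Hyou1 and Acot1.

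After recovery from 30 mg/kg few genes passed (4 arrays against 4). With the 2 arrays of the highest actin ratio left out 19 genes passed in limma, and with all arrays 10. C1qb (0.78 ± 0.14, adjusted p = 0.00784), the adaptor She (0.88 ± 0.19) and hyaluronidase Hyal2 (0.62 ± 0.13) rose, and Kntc1 (-1.73 ± 0.34) and Tmem167a (-0.46 ± 0.10) fell. Camera called up macrophage, endothelial, lymphocyte and plasma protein genes, with 1, 0, 0 and 0 rising of 24, 20, 12 and 28 (6, 4, 1 and 0 up adjusted over the list alone, 9, 7, 2 and 2 at an unadjusted p under 0.05). By camera, adjusted p = 1.39e-08, 0.00269, 0.0495 and 0.0495, and estimated adjusted p = 0.475, 0.513, 0.886 and 0.886. It called down fatty acid synthesis, cell cycle, mitochondrial and cholesterol synthesis genes, with 0 each passing in limma of 19, 40, 30 and 19 (2, 0, 3 and 1 down adjusted over the list alone, 6, 4, 4 and 4 at an unadjusted p under 0.05). In camera, these had adjusted p = 1.89e-06, 0.00513, 0.00513 and 0.0495, and estimated adjusted p = 0.475, 0.886, 0.886 and 0.886. By the naming rule, all 4 treated arrays lay beyond all controls for each gene named. The count of genes became 2 without control replicate 2, 1 without control replicate 3, 1 without control replicate 4, 4 without control replicate 5, 25 without 30 mg/kg replicate 1, 31 without 30 mg/kg replicate 2 and 0 without 30 mg/kg replicate 3. The count of 8 lists became 5 without control replicate 2, 5 without control replicate 3 and 5 without 30 mg/kg replicate 1. Of the limma runs that gave 0 genes, the fit of only the groups compared had 706 genes at an unadjusted p under 0.05, and the fit without 30 mg/kg replicate 3 had 786. Single arrays left out ended the call of C1qb (without 30 mg/kg replicate 3, adjusted p = 0.0925). Of 8 such fits each, calls also ended for She in 5 (adjusted p up to 0.172), Hyal2 in 6 (adjusted p up to 0.084), Kntc1 in 5 (adjusted p up to 0.0741) and Tmem167a in 7 (adjusted p up to 0.182). Otherwise, another filter, offset, probe set or variance choice ended the calls of She, Hyal2, Tmem167a and Kntc1, a fit of only the groups compared those of She, C1qb, Hyal2, Kntc1 and Tmem167a, a replicate block those of She, Hyal2 and Tmem167a, and an actin alternative those of Hyal2.

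**Figure D3:**
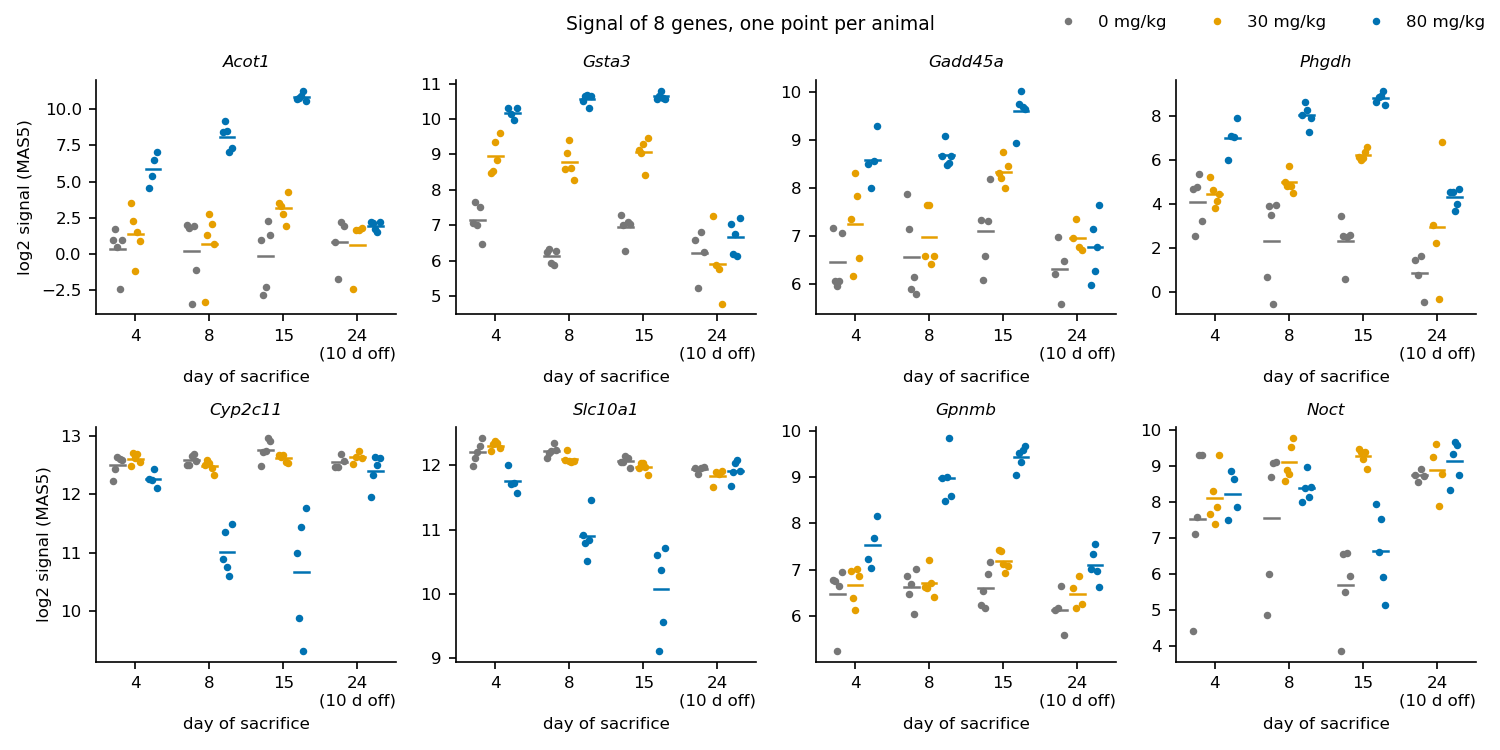
Log2 MAS5 signal of 8 named genes per animal (vertical axis) by day of sacrifice and dose; points are animals and short lines are group means. At 80 mg/kg Acot1 changes by 10.99 (from near the floor, 375-fold with an offset) and Cyp2c11 by -2.10 on day 15, while Noct changes by 3.58 at 30 mg/kg.

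Compared directly, the doses differed most on days 8 and 15. At 80 against 30 mg/kg, 2154 genes passed, 1420 up and 734 down on day 4, 4946 genes on day 8 (3384 up, 1562 down), 5921 on day 15 (3963 up, 1958 down) and 726 on day 24 (487 up, 239 down). At a common median the splits were 558 up and 1233 down, 1487 up and 2608 down, 2820 up and 2500 down and 218 up and 2780 down. With quantile normalization those of day 8 and day 15 were 2365 up and 1849 down and 3088 up and 2381 down. Acot1 was higher at the higher dose on day 4 (4.49 ± 1.07, adjusted p = 0.00198), day 8 (7.40 ± 1.01, adjusted p = 4.32e-08) and day 15 (7.71 ± 1.01, adjusted p = 6.21e-09), or 9.31-fold, 46.8-fold and 148-fold with an offset, as was Gstm3 on day 4 (4.04 ± 0.73). Cox6a2, a muscle-type respiratory subunit, was higher on day 8 (4.29 ± 0.68). Stac3 was lower on day 4 (-2.28 ± 0.43, adjusted p = 0.000163), day 8 (-5.87 ± 0.41, adjusted p = 2.99e-15) and day 15 (-6.76 ± 0.41, adjusted p = 1.55e-18), with Dab1 on day 4 (-2.19 ± 0.44), Inmt on day 8 (-3.76 ± 0.47) and Sds on day 15 (-4.73 ± 0.51). Ugt2b, whose signal had separate high and low levels among animals of the same group, was higher on day 15 (6.04 ± 2.34), although 0 of the 5 arrays at 80 mg/kg lay beyond all those at 30 mg/kg. On day 24 Plac9 (2.90 ± 0.65), the mitotic kinesin Kif2c (2.84 ± 0.70) and Ube2t (2.80 ± 0.78) were higher and Acvr1c (-1.95 ± 0.53) and Zfpm1 (-1.62 ± 0.46) lower.

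Camera called 15, 18, 19 and 13 lists between the doses on days 4, 8, 15 and 24. With an estimated correlation 6 of them passed on day 8, and 0 on the other days, where the smallest adjusted p = 0.246, 0.0537 and 0.161 with an estimated correlation. Those of day 8 were xenobiotic cytochrome P450, bile acid, urea cycle and amino acid, liver transcription factor, pericentral and male-biased genes, with 0, 3, 1, 1, 0 and 0 rising and 20, 16, 27, 11, 9 and 15 falling of 24, 23, 33, 19, 17 and 16 (0, 3, 1, 1, 0 and 0 up and 20, 16, 29, 12, 9 and 15 down adjusted over the list alone). Their camera adjusted p = 4.23e-13, 9.28e-08, 3.35e-17, 3.32e-04, 7.15e-05 and 9.47e-13, and estimated adjusted p = 0.04 each. The fatty acid oxidation list had signs that differed, with median -0.10, mean 0.21, test down on day 4, median -0.17, mean 0.17, test down on day 8 and median 0.02, mean 0.26, test down on day 15. The day 4 count was 1110 without 80 mg/kg replicate 5, and the day 24 count 342 without 30 mg/kg replicate 3 and 385 without 80 mg/kg replicate 2, or 79 with a fit of only the groups compared. Leave-one-out fits ended the call of Ugt2b in 3 (adjusted p up to 0.106), of 10 fits each. On day 24 they ended the call of Plac9 (without 30 mg/kg replicate 3, adjusted p = 0.0557). Of 9 such fits each, calls also ended for Ube2t in 3 (adjusted p up to 0.119), Acvr1c in 4 (adjusted p up to 0.0722) and Zfpm1 in 6 (adjusted p up to 0.0849). For day 24, another filter, offset, probe set or variance choice ended the calls of Ube2t and Zfpm1, and a fit of only the groups compared those of Plac9, Ube2t, Acvr1c and Zfpm1.

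Both doses of a day share control arrays, which makes their effects correlate without any shared response. Across the 10725 genes, which are not independent replicates, the effects at 30 and 80 mg/kg correlated at r = 0.565, 0.488, 0.554 and 0.415 on days 4, 8, 15 and 24. Simulated arrays without any effect but with shared controls gave 0.471, 0.498, 0.501 and 0.527. With the control arrays split between the doses, median r was 0.307, 0.275, 0.411 and 0.0783. The covariance of the effects was 0.0767, 0.0891, 0.156 and 0.0414, against 0.0253, 0.0251, 0.0255 and 0.0318 in the simulations. With the shared controls, genes called up at both doses numbered 49, 18, 253 and 5, where independent calls would give 10.5, 6.49, 113 and 0.358. Genes called down at both numbered 19, 5, 146 and 1, against 2.48, 0.997, 41.3 and 0.154. With split controls the median numbers were 10, 9, 107.5 and 0 up, where independent calls would give 2.07, 3.39, 44.5 and 0.0482, and 0.5, 1, 37 and 0 down, against 0.163, 0.278, 9.4 and 0.

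Whether the 80 mg/kg effect receded after dosing was tested as the effect on day 24 minus that on day 15. The interaction passed for 4578 genes, 1783 up and 2795 down, and at a common median for 1223 up and 3297 down. The effect turned more positive for genes that had fallen: Stac3 (6.84 ± 0.60, adjusted p = 7.12e-13), Sds (4.61 ± 0.75, adjusted p = 1.55e-06), the organic anion carrier Slc22a8 (3.90 ± 0.39, adjusted p = 2.82e-11) and Inmt (3.72 ± 0.68, adjusted p = 1.21e-05). It turned more negative for genes that had risen: Acot1 (-9.83 ± 1.47, adjusted p = 2.96e-07), Cox6a2 (-6.34 ± 0.99, adjusted p = 7.24e-07), Gucy2c (-5.99 ± 1.06, adjusted p = 8.04e-06) and the adaptor Shc4 (-5.15 ± 0.89, adjusted p = 4.32e-06). On day 24 the signal of Acot1 was 3.85 at 80 mg/kg and 1.73 in controls, and that of Stac3 1722 and 2204. Camera called 16 lists, 13 up and 3 down, and 0 with an estimated correlation (smallest adjusted p = 0.173). The strongest upward shifts were in plasma protein (18 of 28 genes rose and 1 fell, 19 and 1 adjusted over the list alone, camera adjusted p = 3.55e-08, estimated adjusted p = 0.325), male-biased (14 of 16 genes rose, 14 adjusted over the list alone, camera adjusted p = 1.18e-08, estimated adjusted p = 0.173) and urea cycle genes (19 of 33 genes rose and 2 fell, 19 and 2 adjusted over the list alone, camera adjusted p = 7.98e-07, estimated adjusted p = 0.297). In these and the other interaction tests, rose and fell mean a more positive or more negative effect on the later day.

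At 30 mg/kg the same interaction passed for 117 genes, 43 up and 74 down. Fgf21 (-2.76 ± 0.54, adjusted p = 0.00519), Gsta3 (-2.42 ± 0.42, adjusted p = 0.00129), Plac9 (-3.44 ± 0.93) and the ATF4 target Trib3 (-2.08 ± 0.51) dropped, and the leukotriene synthase Ltc4s (2.44 ± 0.61) and Apol9a (1.44 ± 0.30) rose. Camera called 7 lists, 1 up and 6 down, and 0 with an estimated correlation (smallest adjusted p = 0.37). The count of genes was 55 without control day 24 replicate 5, 69 without 30 mg/kg day 15 replicate 1, 207 without 30 mg/kg day 15 replicate 4, 44 without 30 mg/kg day 24 replicate 3 and 70 without 30 mg/kg day 24 replicate 4, and 37 with a fit of only the groups compared. For this interaction, leave-one-out fits ended the calls of Ltc4s in 6 (adjusted p up to 0.108), Plac9 in 14 (adjusted p up to 0.134) and Trib3 in 3 (adjusted p up to 0.0589), of 18 fits each. In other settings, another scaling and another filter, offset, probe set or variance choice ended the calls of Plac9, a fit of only the groups compared those of Ltc4s, Plac9 and Gsta3, a replicate block those of Ltc4s, Plac9 and Trib3, and an actin alternative those of Ltc4s and Trib3.

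From day 4 to day 15 the 80 mg/kg effect changed for 2618 genes, 1539 up and 1079 down. Acot1 (5.42 ± 1.47, adjusted p = 0.00472), Cox6a2 (4.87 ± 0.99, adjusted p = 0.000212) and Phgdh (3.59 ± 1.03, adjusted p = 0.00789) moved up, and Stac3 (-4.30 ± 0.60, adjusted p = 6.06e-07) and Akr1b7 (-4.29 ± 1.46, adjusted p = 0.0256) moved down. RT1-T24-4, a class I histocompatibility gene with separate high and low levels among animals, also passed (7.56 ± 2.87). All 12 camera calls were downward, led by plasma protein (25 of 28 genes fell, 26 adjusted over the list alone, camera adjusted p = 1.79e-17, estimated adjusted p = 0.106), male-biased (1 of 16 genes rose and 13 fell, 1 and 14 adjusted over the list alone, camera adjusted p = 3.23e-10, estimated adjusted p = 0.101) and bile acid genes (3 of 23 genes rose and 12 fell, 3 and 14 adjusted over the list alone, camera adjusted p = 1.11e-06, estimated adjusted p = 0.101). Leave-one-out fits also ended the call of Akr1b7 (without control day 4 replicate 3 or 80 mg/kg day 4 replicate 3, adjusted p = 0.0541 and 0.0625). Of 19 such fits each, calls also ended for RT1-T24-4 in 14 (adjusted p up to 0.15). In other settings, another scaling and another filter, offset, probe set or variance choice ended the calls of RT1-T24-4, a replicate block those of Akr1b7, and an actin alternative those of RT1-T24-4 and Akr1b7.

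Some array measures moved with dose or day. The median log2 signal of the array was higher at 80 mg/kg than in controls on day 8 (4.22 against 4.00), day 15 (4.13 against 4.00) and day 24 (4.33 against 4.07), each with a two-sided exact permutation p = 0.00794 and a Benjamini-Hochberg adjusted p = 0.0212 over 8 comparisons. On day 4 the exact permutation p = 0.0714. The 3'/5' log2 ratio of beta-actin probe sets, a measure of RNA integrity, fell by 0.31 at 80 mg/kg on day 15 (exact permutation p = 0.00794, adjusted p = 0.0635). It lay between 2.55 and 3.29 in the 13 arrays of day 24 and between 1.91 and 2.67 in the 44 others. The bioB spike control lay between 7.04 and 8.28 on days 4 and 8 and between 3.78 and 5.56 on days 15 and 24, so that a technical difference between days cannot be told apart from the day.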

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

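The tests of the marker pattern on day 24 were chosen after its result was seen, while the tests of single extreme arrays, of interactions and of other splits of the arrays were planned.

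A single array stood apart in 26 of 451 pairs of a named gene and a group, and in 4 of 48 pairs of an array measure and a group, judged by Dixon's gap to the nearest array over the group's range. Chance gives about 1 in 20 such groups. In control on day 15 these were Abcc4 in replicate 1 (highest, 0.805), C9 in replicate 1 (lowest, 0.718), Ggt1 in replicate 2 (lowest, 0.847), Sdf2l1 in replicate 3 (highest, 0.78) and the actin 3'/5' ratio in replicate 5 (highest, 0.741). For 30 mg/kg on day 15 they were Akr7a3 in replicate 4 (lowest, 0.776). In 80 mg/kg on day 15 these were Asl in replicate 1 (lowest, 0.858), RT1-T24-4 in replicate 1 (lowest, 0.936), Ttk in replicate 5 (highest, 0.754), the median log2 signal in replicate 2 (highest, 0.736) and the bioB control in replicate 5 (highest, 0.726). For control on day 24 they were Apol9a in replicate 2 (highest, 0.865), Epcam in replicate 3 (lowest, 0.906), Pecam1 in replicate 5 (lowest, 0.917) and Tmem167a in replicate 5 (highest, 0.85). In 30 mg/kg on day 24 these were Kif2c in replicate 3 (highest, 0.894) and the bioB control in replicate 1 (lowest, 0.863). For 80 mg/kg on day 24 they were Serpina7 in replicate 1 (lowest, 0.739), Shc4 in replicate 3 (highest, 0.717) and Stac3 in replicate 3 (lowest, 0.761). In control on day 4 these were Gpnmb in replicate 3 (lowest, 0.823), Scd in replicate 5 (lowest, 0.766) and Sel1l in replicate 4 (lowest, 0.743). For 80 mg/kg on day 4 they were Cldn4 in replicate 5 (highest, 0.849), Fas in replicate 2 (lowest, 0.858) and RT1-T24-4 in replicate 3 (lowest, 0.902). In 80 mg/kg on day 8 these were Ccna2 in replicate 4 (highest, 0.767), Gucy2c in replicate 5 (lowest, 0.731), Hao2 in replicate 4 (lowest, 0.782) and Nox4 in replicate 4 (lowest, 0.923).

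Effects differed between days by the interaction test. At 80 mg/kg, 4578 genes and 16 lists differed between days 24 and 15, with the named differences in log2 of Stac3 (6.84), Sds (4.61), Slc22a8 (3.90), Inmt (3.72), Acot1 (-9.83), Cox6a2 (-6.34), Gucy2c (-5.99) and Shc4 (-5.15). At 30 mg/kg, 117 genes and 7 lists did, with Ltc4s (2.44), Apol9a (1.44), Plac9 (-3.44), Fgf21 (-2.76), Gsta3 (-2.42) and Trib3 (-2.08). From day 4 to day 15 at 80 mg/kg, 2618 genes and 12 lists did, with RT1-T24-4 (7.56), Acot1 (5.42), Cox6a2 (4.87), Phgdh (3.59), Stac3 (-4.30) and Akr1b7 (-4.29). These lists are camera's at the preset correlation. With an estimated one it called 0 in each case (smallest adjusted p = 0.173, 0.37 and 0.101), and fry called 19, 0 and 14. Outside the genes tested, 1903 of 4336 probe sets without a single gene symbol were called at 80 mg/kg on day 15, or 43.9%.

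The arrays of each comparison were split in other ways into groups of the same sizes. In 1 of 100 splits, the real one, as many genes were called, so that chance is unlikely (unadjusted), for these real counts. At 80 mg/kg against control they were 2952 (highest other 2147), 5446 (highest other 3540), 6354 (highest other 4344) and 1097 (highest other 995) on days 4, 8, 15 and 24. At 30 mg/kg against control they were 84 (highest other 25), 25 (highest other 4) and 493 (highest other 169) on days 4, 8 and 15. Between the doses they were 2154 (highest other 1487), 4946 (highest other 3255), 5921 (highest other 3880) and 726 (highest other 565). For 30 mg/kg on day 24, 2 of 35 splits gave as many as the real 10 (highest other 10), and chance is not excluded. For the 80 mg/kg effect on day 24 against day 15, 2 of 100 splits gave as many as the real 4578 (highest other 4591). For the same interaction at 30 mg/kg, 8 of 100 splits gave as many as the real 117 (highest other 2134). Their highest splits kept the treated arrays together and changed 2 and 6 controls. Days were exchanged within treated and control arrays, so day differences could enter the counts. Chance is thus excluded for neither.

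On day 24 at 80 mg/kg, markers of macrophages, stellate, biliary and endothelial cells lay above control, with a median log2 fold change of 0.56 over 92 genes. As the whole cause, only a constant shift per array is excluded. At a common array median the median was 0.30 (0.3047), exact permutation p = 0.0159 over 126 splits. Quantile normalization gave list medians of 0.28 to 0.62 (untested). The actin 3'/5' ratio did not account for the pattern, since the median was 0.53 (0.5307) with the ratio as a covariate over all arrays. The mean log2 ratio at 80 mg/kg minus control was -0.21 for actin and 0.04 for GAPDH. These ratios alone cannot exclude RNA degradation. A lower share of hepatocytes stays open. It would raise all other cells' markers alike, and the mean shifts were 0.58 for macrophages, 0.48 for stellate cells, 0.75 for biliary cells, 0.35 for endothelial cells and 0.63 for lymphocytes. Their range of 0.40 (highest other split 0.42) had an exact permutation p = 0.0238, but p = 0.111 with the offset and p = 0.444 over the 73 of 104 members above the median of all values in each array, and genes near the floor need not shift alike. A change in the cells themselves cannot be told apart from it.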

How the results depend on the processing

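The actin covariate and the day 24 runs without 2 arrays were chosen after seeing the data, the others planned. No named gene reversed in any setting. Other probe sets differed in sign only for Gpt2 (0.22, 80 mg/kg day 4) and She (-0.06, 30 mg/kg day 24), uncalled. At a common median these calls turned from more rises to more falls. At 80 mg/kg on days 4, 8 and 24 they were 943 up and 1596 down, 1772 and 2996, and 267 and 3359. Between the doses they were 558 and 1233, 1487 and 2608 and 218 and 2780. The cause was not tested. Of 213 named results of 2 groups, 64 had a group's mean signal under the median of all values, 15 of them in both groups, and with the offset their log2 changes were 40.9% to 93.5% as large (median 74.3%). Counts below moved by more than 1.5 times, the cause again not tested. With quantile normalization the genes of 30 mg/kg on day 24 were 18, and the lists of day 24 were 7 at 80 mg/kg and 5 at 30 mg/kg. At a common median the genes were 3626 for 80 mg/kg on day 24, 39, 14, 300 and 5 for 30 mg/kg on days 4, 8, 15 and 24, 2998 between doses on day 24 and 57 for the 30 mg/kg interaction. For 30 mg/kg on day 24, no filter gave 2 genes, the stricter filter 4 lists and the offset 5 lists. With all probe sets 9787 were called for 80 mg/kg on day 15, 8892 between doses on day 15, and 198 and 6 for 30 mg/kg on days 4 and 24, with 12 lists on day 4. Array weights gave 70, 1002 and 3 genes for 30 mg/kg on days 8, 15 and 24. A fit of only the groups compared gave 2 genes and 13 lists for 30 mg/kg on day 4, 8 genes on day 8 and 0 genes in limma on day 24 (706 at an unadjusted p under 0.05), 79 between doses on day 24 and 37 for the 30 mg/kg interaction. The added tests gave 19 genes for 30 mg/kg on day 24 without the 2 arrays, and with the covariate 52 genes for 30 mg/kg on day 4 and 5 lists on day 8. With split controls the doses' effects had r = 0.307, 0.275, 0.411 and 0.0783.

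With an estimated correlation camera called 2 lists for 80 mg/kg on day 4 and 0 in each other comparison with control. At an unadjusted p under 0.05 these had 10, 7 and 5 lists at 80 mg/kg and 3, 2, 2 and 2 at 30 mg/kg. With fry the lists were 7 for 80 mg/kg on day 4 and 7 on day 24, and 3, 1, 5 and 0 for 30 mg/kg, the last with 3 at an unadjusted p under 0.05.

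In leave-one-out fits the genes called ranged over 2064 to 2985, 5013 to 5382, 5969 to 6206 and 611 to 1277 for 80 mg/kg on days 4, 8, 15 and 24. For 30 mg/kg they ranged over 19 to 87, 12 to 43, 277 to 616 and 0 to 31, the 0 in limma without 30 mg/kg day 24 replicate 3 with 786 at an unadjusted p under 0.05. Between doses they ranged over 1110 to 2266, 4491 to 4942, 5547 to 5827 and 342 to 846. For the interactions they ranged over 4269 to 4537 at 80 mg/kg and 44 to 207 at 30 mg/kg for day 24 against day 15, and 2144 to 2765 for day 15 against day 4. Lists ranged over 10 to 12, 18 to 19, 15 to 18 and 12 to 15 at 80 mg/kg and 4 to 13, 5 to 9, 7 to 13 and 5 to 9 at 30 mg/kg.

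Of 233 results for named genes, 181 kept their call in every setting that gave a value and 52 lost it in at least 1. The calls lost were 11 with quantile normalization, 12 at a common median, 10 with no filter, 5 with the offset, 7 with the mean of probe sets, 7 with all probe sets, 5 without the trend, 2 with array weights, 29 with only the groups compared, 10 with the covariate and 5 without the 2 day 24 arrays. Leave-one-out fits lost 203 and kept 2225. Under the stricter filter 160 results had a value and kept their call, and the rest had no value.

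Replicate numbers did not pair the arrays of a day: residuals of arrays with the same number in 2 doses had mean correlations from -0.0282 to 0.0306. With the number as a block within each day, 30 mg/kg had 15 genes on day 8, 6 on day 24 and 60 for the interaction, and 13 named results lost their call.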

Other observations

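The tests in this part were chosen after the results were seen, except that of a single array behind the 30 mg/kg pattern, which was planned. On day 15, 27 of the 88 genes called and changed at least 2-fold at 30 mg/kg changed less at 80 mg/kg. The 27 were chosen by these values, so their number is no test of a smaller effect at 80 mg/kg.

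A single array behind this pattern is excluded, since at least 20 of the 27 genes were still called with any 1 array left out. An order of the animals that the replicate numbers follow stays open. Within the control groups the set's score correlated with the number over 19 arrays (each centred on its group, Pearson's r = 0.885, permutation p = 9.999e-05, Spearman's rho = 0.903, permutation p = 9.999e-05, Benjamini-Hochberg adjusted p = 0.00019998 over 2 correlations, and r = 0.884 without the 2 arrays farthest from the median number). Within the treated groups r was 0.355 (permutation p = 0.058594, adjusted p = 0.058594). For the number, limma called 111 genes in the controls, 12 of them in the set, and 1 in the treated arrays. Of the 493 genes of 30 mg/kg on day 15, 23 were among the control ones, 21 with the same sign, and for 80 mg/kg 84, 20 with the same sign. The labels do not say what the numbers stand for. The time of day at sacrifice stays open. The 16 clock genes outside the set had a median absolute log2 fold change of 0.18 (0.1828), but 2 of them and Noct, in the set, were called, and camera called the clock list up, a call lost with an estimated correlation (estimated adjusted p = 0.387). A state that varies between animals at any dose, such as feeding, also stays open. The set's residuals correlated at a mean of 0.1585 over 19 control arrays (highest of 1000 random sets 0.058). Food intake and time of sacrifice per animal would test these hypotheses.

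In 5 genes, named after their values were seen, arrays of the same group fell into 2 signal levels at least 2 log2 units apart. They were Ugt2b (low in 15 arrays, high in 42), Ubd (20, 37), RT1-T24-4 (15, 42), RT1-Bb (12, 45) and RGD1309362 (22, 35). Noise of dim probe sets is excluded, since the higher level lay above 4 times the median of all values in all 5 genes. Pooled over days, the lower level was spread unevenly over doses for 0 of 5 genes (Fisher's exact test, adjusted or unadjusted p under 0.05). An effect on 1 day stays open, as limma called RT1-T24-4 higher on day 15 (6.39 at 30 and 6.02 at 80 mg/kg). A sequence variant shared by neighbouring genes could not be tested by the number of pairs within 1 Mb, which was 0 and is also the 95% point for random sets. Linked variants on chromosome 20 are a candidate explanation for Ubd and RT1-T24-4, which were both high in 35 arrays and both low in 13 (Fisher's exact test, adjusted p = 2.41e-05 over 10 pairs), while the smallest adjusted p for genes on different chromosomes was 0.22. The other 2 pairs on that chromosome, of RT1-Bb with Ubd and with RT1-T24-4, did not go together (adjusted p = 0.203 and 0.38). Genotyping of the animals at these genes would test this hypothesis.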
